A study of Macaca mulatta with 3 samples.

How the data were processed

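Chromatin from the prefrontal cortex (superior frontal gyrus) of 1 male rhesus macaque aged 3389 days was sonicated and precipitated with an antibody against trimethylated lysine 4 of histone H3 (H3K4me3), a mark found at active transcription start sites. Fragmented DNA of the same tissue that skipped the precipitation served as input. Both libraries were sequenced as single-end tags of 36 bases, per the labels' protocols. A pool of RNA from 5 males was also sequenced; it was not analysed here.

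The authors deposited 1 line per aligned tag for each library, with its position, its strand, a code and a score, so tags were counted here from those lines. The deposited score was 0 in every line and was not used. The ChIP tags all spanned 36 bases and carried the codes U0, U1 or U2. The input tags all spanned 38 bases, carried U0 alone, and no position and strand occurred more than once, so the deposited libraries had not been filtered alike. These codes resemble those of aligners that mark a unique match by its number of mismatches, but no label says so. The authors also deposited 1 list of peaks for the ChIP library, with a p-value or q-value per peak, all below 0.001; whether it was adjusted is not stated. TopHat and SICER are named in the submitters' processing notes, with no version and no role. The aligner of these tags and the genome build are not given in the sources used here.

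Coordinates are those of the deposited files, written from 1. On 19 of 21 chromosomes the gene table used for comparison held genes over 1 Mb beyond the last tag, so it describes another assembly and no gene was assigned. Transcription start sites, gene lists, sequence content and peaks away from genes were therefore not analysed here.

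Each tag was placed at its 5' end and counted in each deposited peak. The ratio of a peak is its ChIP tags over its input tags, divided by the ratio of the library totals (1.09). A peak without an input tag was given 3 tags there, so its ratio is a lower bound. Each peak was tested with a two-sided exact binomial test of ChIP against input tags, adjusted by Benjamini-Hochberg over 24248 peaks, and counted as enriched at an adjusted p below 0.05 and a ratio of at least 2. The test compares these 2 libraries, not conditions. There is 1 library of each kind, so no difference has a replicate check. Intervals of shares and ratios are exact Clopper-Pearson intervals at 95%, and those of medians come from order statistics. Those of shares and ratios cover counting error only, and PCR tags are not independent molecules. Those of medians reflect the spread between peaks, which are treated as independent. Neither kind covers variation between animals or libraries.

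Chromosome lengths were taken as the last base covered by a tag. Peaks were placed at random on their own chromosomes 100 times to describe spacing. Peaks named by position follow a rule fixed before the data were examined: the 10 widest, the 10 of highest ratio with at least 100 ChIP tags and the 5 with most input tags. High-input peaks are those where the input exceeded 10 times its genome mean; this class was defined after the data were examined. Correlations across chromosomes used permutation tests with 100000 resamples. The offset between strands was the lag, searched from 60 to 300 bases, that gave most pairs of plus- and minus-strand tags within peaks.

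The recount was tested on simulated tags for the 24248 peaks. It called 2% of 50 sites with a true ratio of 2, 38% of those with 4, 86% with 8 and 98% with 16, and 1 of 24048 unchanged sites. With every peak set at a ratio of 2, 4 or 8, it called 10.7%, 78.3% or 97.0% of peaks. Settings chosen beforehand for comparison were 1 tag per position and strand, tags moved 75 bases downstream, autosomes and X only, scaling by tags outside peaks, a ratio of at least 4, at least 20 ChIP tags, peaks under 1 kb apart merged, the widest 10% of peaks, the 25% of peaks with most ChIP tags, and tags outside peaks for X. Others, chosen after the data were examined, used only distinct ChIP tags of code U0, left out high-input peaks, thinned both libraries to 50%, or measured spacing after merging peaks under 1 kb apart, with random gaps under 1 kb left out. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.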

Results

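The study mapped H3K4me3 in the macaque prefrontal cortex to locate transcription start sites. Its chromatin data comprised 1 ChIP library of 10023993 tags and 1 input library of 9162762 tags from the same animal. In the ChIP library 80.6% of tags had the code U0, 16.2% had U1 and 3.27% had U2, whereas all input tags had U0. Repeated positions made up 0.343% of ChIP tags.

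The deposited list held 24248 H3K4me3 peaks on 20 autosomes and X, covering 30.5 Mb or 1.06% of the genome span. Peaks had a median width of 1000 bases (interquartile range 800 to 1600). They lay close together: neighbours were a median of 38.2 kb apart, against 69.9 kb on average over 100 random placements on the same chromosomes (range 68.8 to 71.2). Of 24227 neighbouring pairs, 18.9% were within 5 kb, against 6.51% when placed at random (range 6.12 to 6.83). Of the 4571 pairs within 5 kb, 2015 were under 1 kb apart. With such pairs merged, 22233 peaks were left, a median of 46.2 kb apart against 79.2 kb when placed at random, and 11.5% of pairs were within 5 kb against 3.85%.

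ChIP tags were more concentrated in these peaks than input tags. The peaks had been listed for ChIP excess in this same library, so the direction of the following values was largely set by that selection. The peaks held 8.56% of ChIP tags (exact Clopper-Pearson interval 8.54 to 8.58) and 2.74% of input tags (2.73 to 2.75). A typical peak held 23 ChIP tags and 6 input tags at the median, and 443 peaks held no input tag. The median ratio of ChIP to input was 3.76 (3.66 to 3.81), with an interquartile range of 2.74 to 5.55. Tags peaked at the centres of the 24062 peaks that were not high in input. There the ChIP library reached 2.73 tags per 100 bases, 4.37 times its level at 2.5 kb and beyond, and the input rose by a factor of 1.36.

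**Figure D1:**
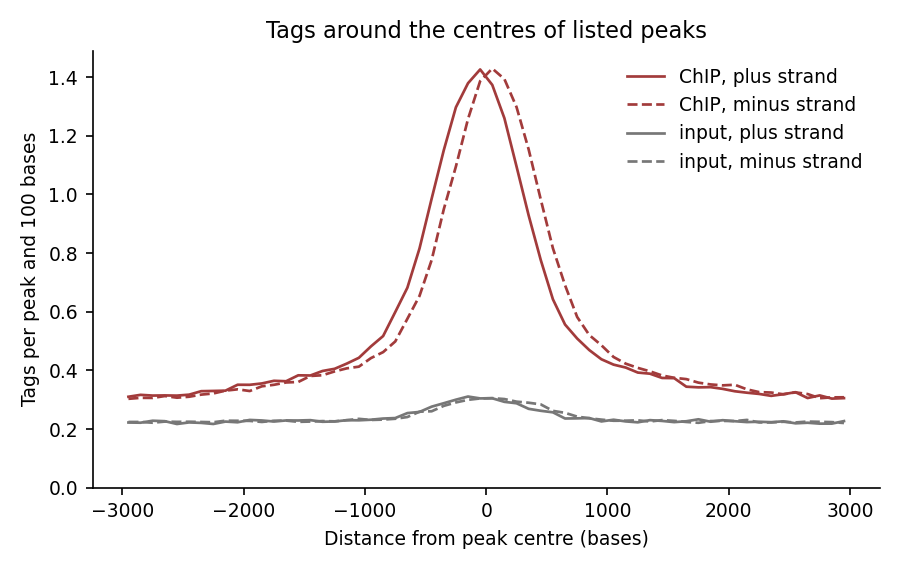
Mean number of tags per peak and 100 bases (vertical axis) by distance from the peak centre in bases (horizontal axis), for each strand of the ChIP and input libraries over 24062 peaks. Both ChIP strands rise at the centre, the plus strand slightly upstream of the minus strand, and the input rises far less.

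On recount, 18760 of the 24248 peaks (77.4%) were enriched in the ChIP library, by the exact binomial test with Benjamini-Hochberg adjustment. Without the condition on the ratio 19395 passed, and 20183 had an unadjusted p below 0.05. The peaks had been listed for ChIP excess in this same library, so this count describes the list and is no independent check; a call toward the input was largely excluded by that selection, and none was made. The deposited value had a Spearman correlation of 0.937 with a Poisson tail recomputed from the same tags, over the 23805 peaks with an input tag, and of 0.982 over 23826 with tags moved 75 bases. Ratios of at least 4 were found at 11079 peaks and of at least 8 at 2776, while 1493 peaks with an input tag had a ratio under 2. A further 36 without an input tag had a lower bound under 2, which leaves their ratio open; 23 of them passed the adjusted p and were not counted as enriched. Counting the strands separately, 15977 peaks (65.9%) reached a ratio of 2 on both. Across peaks, which are not independent replicates, the ratios of the strands had a Spearman correlation of 0.155, and of 0.461 over the 2640 peaks with at least 60 ChIP tags and no high input. Close ranks of single peaks by ratio were not resolved at this depth.

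Among peaks with at least 100 ChIP tags, the steepest lay on chromosome 6 at 92633401 to 92635600, with 1062 ChIP tags against 9 input tags, a ratio of 108 (56.6 to 237). Of its ChIP tags 65.0% carried U1 or U2, and its edges were steep: the adjoining 1 kb held 15 tags on the left and 0 on the right, while each 200-base step inside held 11 to 179. The other peaks of highest ratio with at least 100 ChIP tags had lower ratios, though the highest of them overlapped in interval. Among these, chromosome 5 carried the next in order, at 135929801 to 135931400 with a ratio of 19.2 (7.97 to 60.3) and at 95807201 to 95810200 with 16.1 (7.57 to 40.8). A peak of 0.4 kb on chromosome 20 at 29767401 to 29767800 had a ratio of 15.9 (8.44 to 33.8), with 34.5% of its ChIP tags coded U1 or U2 and input at 7.81 times the genome mean. The remaining 6, on chromosomes 3, 4, 9, 13 and 14, had ratios from 11.5 to 12.7, and all of these intervals overlapped.

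**Figure D2:**
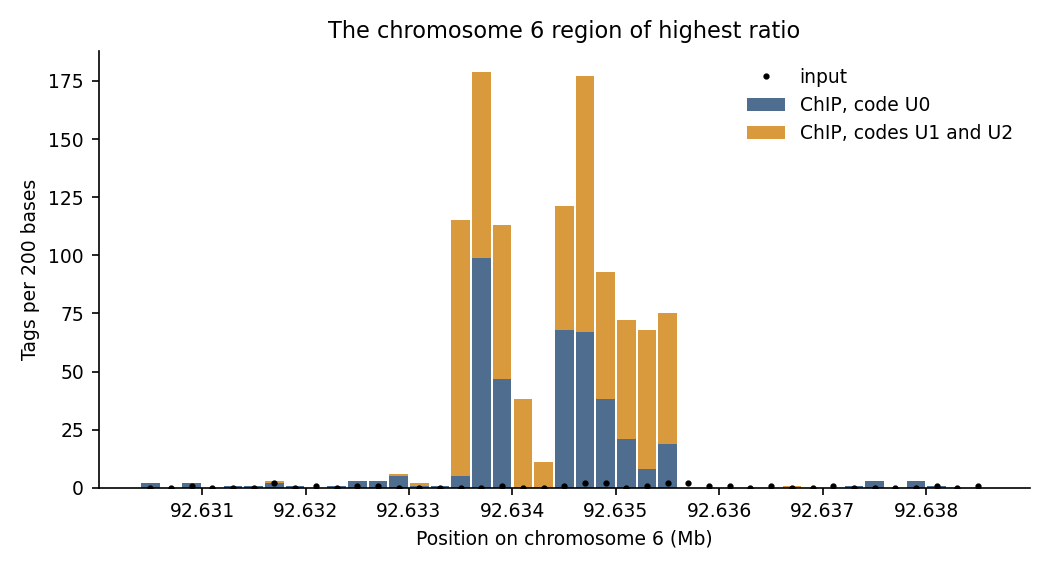
Tags per 200 bases (vertical axis) along chromosome 6 in Mb (horizontal axis) around the peak of highest ratio, with ChIP tags stacked by code and input tags as points. ChIP tags fall steeply at both edges of the peak, to 15 in the 1 kb on the left and 0 on the right, and U1 and U2 tags make up 65.0% of those inside.

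Width and enrichment parted at the far end of the range. The widest peaks, at or above the 95th percentile of 2600 bases (1501 peaks, or 6.19% because of ties), had a median ratio of 3.85 (3.71 to 3.95), against 3.74 (3.66 to 3.81) in the others, so their intervals overlapped. Among the 10 widest, from 15.6 to 25.2 kb, ratios were only 1.16 to 1.35 and none was called enriched. Each failed on the ratio of 2 alone: by the binomial test all had more ChIP than input, with adjusted p of 8.51e-05 or less. The widest was on chromosome 8 at 8580601 to 8605800, with 2314 ChIP and 1821 input tags. Chromosome 15 at 5297201 to 5315200 held 5176 and 3762, and chromosome 8 at 9001 to 27000 held 5115 and 3847. Other wide regions were chromosome 6 at 108794401 to 108813600 with a ratio of 1.26, chromosome 11 at 11280001 to 11298800 with 1.19, and chromosome 3 at 32954801 to 32970400 with 1.35. The 5 peaks with most input tags, on chromosomes 8, 9 and 15, had input at 41.7 to 185 times the genome mean and ratios of 1.18 to 1.35.

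All of these wide regions belonged to the 186 high-input peaks. That class made up 0.767% of peaks but held 12.05% of the ChIP tags and 27.7% of the input tags found in peaks. Its median ratio was 1.54 (1.495 to 1.594), and 26 of its peaks were called enriched. These ratios count repeated ChIP positions, whereas the input file holds none. In the named peaks of the class, distinct positions were 84.3% to 94.5% of ChIP tags, so part of their ratio can stem from this unlike filtering. U1 and U2 tags were 60.7% of the ChIP tags of the class, against 21.9% in the other peaks. With distinct U0 tags alone its median ratio was 0.962 (0.925 to 1.02), and that of the 10 widest peaks was 0.485 (0.394 to 0.595). Of the 186, 61 had a U0 ratio whose interval lay below the 0.948 found outside peaks and 37 one above it. Chromosome 9 held 28 of these peaks, chromosomes 3 and 14 held 21 each, and chromosome 8 held 19. Without this class, the peaks of at least 2600 bases had a median ratio of 3.98 (3.87 to 4.09) and the others 3.76 (3.66 to 3.81). The ratio did not rise steadily with width: without high-input peaks it was 3.96 (3.66 to 4.11) at 200 to 400 bases, 3.66 at 600 to 800 and at 1000 to 1400, and 4.08 (4.02 to 4.15) at 1600 to 2400.

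**Figure D3:**
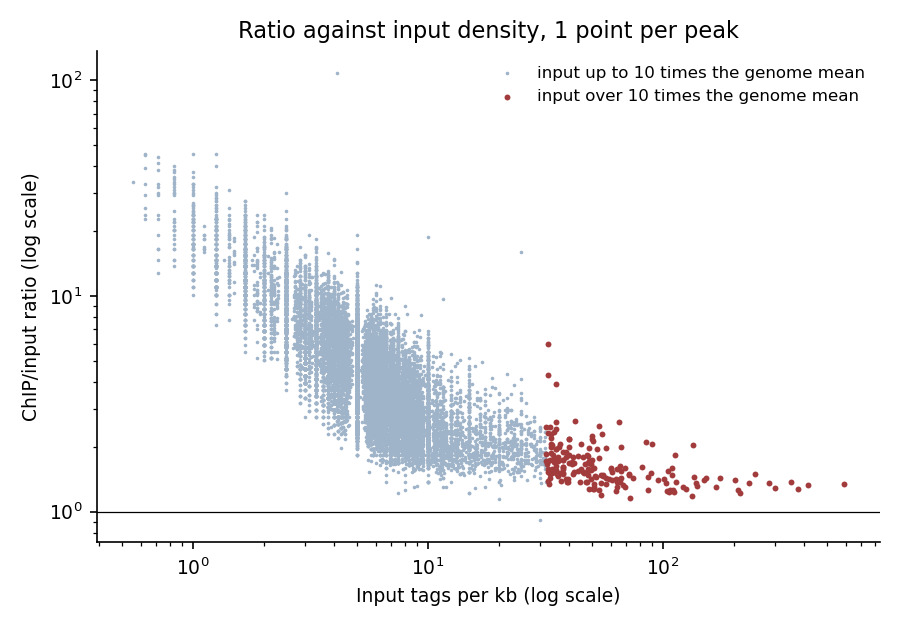
Ratio of ChIP to input (vertical axis, log scale) against input tags per kb (horizontal axis, log scale), 1 point per peak with an input tag. The 186 high-input peaks have a median ratio of 1.54; the input enters both axes, so part of the downward slope follows from the calculation.

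Peak density differed 7.06-fold between autosomes. Chromosome 19, the counterpart of the gene-dense human chromosome of that number, had 29.8 peaks per Mb. Chromosome 16 followed with 18.99, chromosome 10 with 14.6 and chromosome 20 with 12.4, and chromosome 5 was lowest with 4.22. The densest megabase was chromosome 19 from 63000001 to 64000000 with 75 peaks, followed by chromosome 14 from 8000001 to 9000000 with 72. Of 2799 megabase windows with at least 1000 input tags, the median held 6 peaks and 265 (9.47%) held none. Of the 53 windows with at least 40 peaks, 16 were on chromosome 19. The longest stretches without a peak, among those with input at no less than 50% of the genome mean, were chromosome 5 from 25616201 to 32227800 (6.61 Mb) and chromosome 6 from 22940801 to 29099400 (6.16 Mb).

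Chromosomes with more peaks also had more ChIP signal outside them. The ratio outside peaks was 1.16 on chromosome 19, 1.02 on chromosome 16 and 0.886 on chromosome 5. Over the 20 autosomes it rose with peaks per Mb, with a Pearson r of 0.982 and a Spearman rho of 0.971. Both had a permutation p of 2e-05, two-sided, the smallest the 100000 resamples can give, and the same adjusted p over these 2 statistics of 1 relation. Without chromosomes 16 and 19, r was 0.932. Autosomes of 1 animal are not independent samples of animals. Both quantities also came from the same tags. The ratio outside peaks included their flanks, where it was raised (1.16 in windows within 1 kb without high input). More peaks can therefore raise it by themselves, and these p-values do not show an independent relation.

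**Figure D4:**
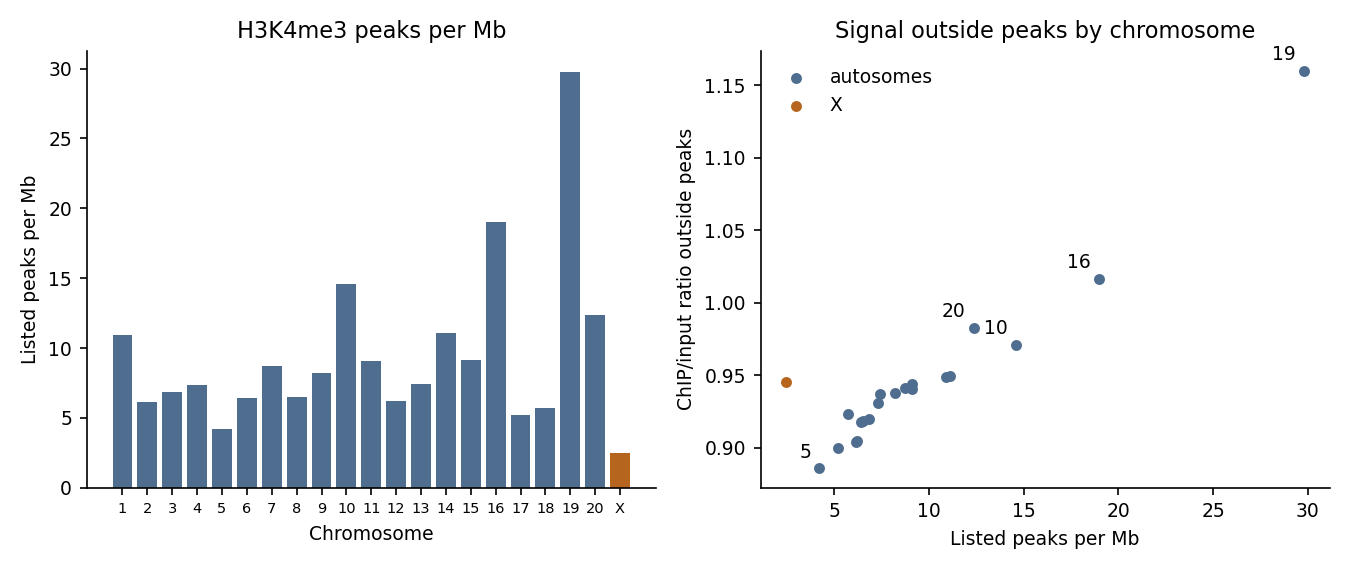
Left, listed peaks per Mb (vertical axis) by chromosome; right, ratio of ChIP to input outside peaks (vertical axis) against peaks per Mb (horizontal axis), 1 point per chromosome. Chromosome 19 is highest on both at 29.8 peaks per Mb and a ratio of 1.16; no error bars are drawn.

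The ratio fell with distance from the peaks. In windows of 1 kb without high input it was 1.16 (1.16 to 1.17) within 1 kb of a peak, 1.07 at 1 to 2 kb, 0.982 at 5 to 10 kb and 0.849 (0.845 to 0.852) beyond 500 kb. Input density fell as well, from 4.41 to 1.75 tags per kb. Of 2771493 windows at least 1 kb from any peak, the 2503624 with at least 1 tag in either library were tested, and 2 were called higher in ChIP and 2 higher in input by the binomial test with Benjamini-Hochberg adjustment, with 54219 at an unadjusted p below 0.05. The 2 higher in ChIP were on chromosome 15 at 93902001 to 93903000, with 320 ChIP and 137 input tags, and on chromosome 9 at 70777001 to 70778000, with 199 and 90; they were named after their values were seen. Both were high in input, and with distinct U0 tags no window was higher in ChIP and 91 were higher in input. These counts do not exclude enrichment outside the list. The peaks of this same library had already been taken out, which left few windows to call. The genome means were only 3.50 ChIP and 3.20 input tags per kb, and the power of the test in windows was not simulated.

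**Figure D5:**
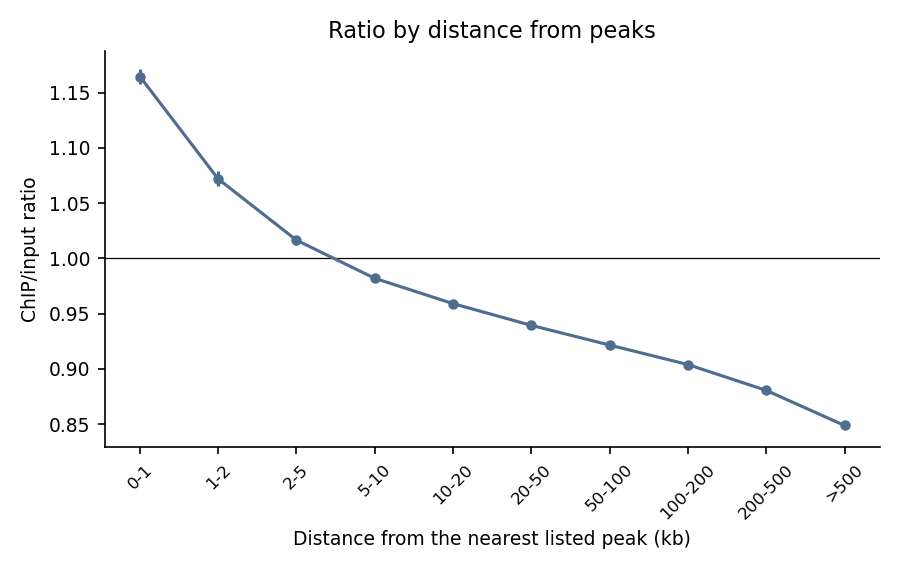
Ratio of ChIP to input (vertical axis) in 1-kb windows by distance from the nearest listed peak in kb (horizontal axis); bars are exact 95% intervals for counting error. The ratio falls from 1.16 beside peaks to 0.849 beyond 500 kb.

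On X, of which a male has a single copy, tag density was 0.425 of the median autosome in the ChIP library (0.424 to 0.427) and 0.435 in the input (0.433 to 0.437). Peaks were scarcer still, at 2.48 per Mb against an autosomal median of 7.81, a factor of 0.318. Peaks on X had a median ratio of 5.64 (5.18 to 6.40), above the autosomal medians of 3.352 to 4.205. They held a median of 3 input tags, against 5 to 6 on autosomes, and with fewer tags a peak needs a higher ratio to pass a fixed threshold. Outside peaks the ratio on X was 0.945, within the autosomal range of 0.886 to 1.16.

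Over all peaks, the smoothed number of pairs of plus- and minus-strand tags had a maximum at 36 bases, the length of a tag, a minimum at 78 and a lower, local maximum at 113 bases. The local maximum at 113 bases was also found with 1 tag per position and strand, in the 25% of peaks with most ChIP tags and without high-input peaks. Within the range searched from 60 bases the count over all peaks was highest at that lower limit, on the falling side of the maximum at 36.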

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

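The tests on high-input peaks and on chromosome 6 were chosen after those results were seen; the test on X was set beforehand.

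The ChIP library held 11592 tags on an unplaced sequence named chrUr where the input had none, 0.116% of its tags. The files were not filtered alike, so this absence does not measure a difference in signal. They drew attention because no peak or chromosome compared here lies on that sequence, although they count in the library total; 43.2% of them (42.3 to 44.1) carried U1 or U2. Codes U1 and U2 made up 19.4% of all ChIP tags and none of the input tags, again with no counterpart in the input file. Their share was 18.8% outside peaks.

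The 186 high-input peaks had a median ratio of 1.54, which counts repeated ChIP positions although the input file holds none. With distinct U0 tags alone the median was 0.962 with an upper bound of 1.02, while the ratio outside peaks was 0.948. These values do not settle the matter, because U0 tags without enrichment should lie near 0.948, and 61 of the 186 peaks lay below it beyond their intervals, with a median of 0.485 in the 10 widest. Restricting the ChIP library to U0 is therefore not a like-for-like comparison with this input. Neither H3K4me3 at these sequences nor the keeping of U1 and U2 tags in the ChIP library alone would by itself put U0 ratios below that level. Whether U0 means the same in both files is not stated, so these explanations cannot be told apart here.

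The peak on chromosome 6 at 92633401 to 92635600 held 1062 ChIP tags. Amplification of a few molecules is argued against by 966 distinct positions and strands among its tags, or 91.0% of their number. Extra exact copies in this animal are argued against by an input density of 1.28 times the genome mean. Its share of U1 and U2 tags, 65.0%, exceeded that of 99.1% of 431 comparison peaks, which is consistent with tags from a diverged sequence being assigned here. A genomic source of that kind would still have to explain a U0 ratio of 46.9 against this input. H3K4me3 at this locus alone stays open, since 4 comparison peaks had as high a share. Whether the tags of those 4 peaks came from their own loci was not tested, so their share does not show what a single locus gives.

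X held 2.44 peaks per Mb (exact Poisson interval 2.20 to 2.70) that passed a recomputed Poisson tail of 0.001, with tags moved 75 bases and at least 1 input tag assumed. With autosomal tags thinned to 43.5%, the density of input on X, in 100 draws, X stood at 0.521 of the median autosome, against 0.333 at full depth. This change cannot be credited to depth, because only listed peaks were scored. Peaks on X were scored on the tags that had listed them, and 98.4% passed. Autosomal peaks listed at full depth were scored on thinned tags, and 59.8% passed. That unlike selection can raise X against the autosomes by itself. By the expectations set beforehand, fewer tags alone would bring X to at least the median thinned autosome. X stayed below that median, 4.69 per Mb (range over draws 4.56 to 4.81), a shortfall that a selection raising X does not explain. A narrower set of marked sites would put X below the lowest thinned autosome. That one had a median of 2.67 (range over draws 2.52 to 2.87), inside the counting error of X. Neither expectation was met, so fewer tags and a narrower set of marked sites on X cannot be told apart here.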

How the results depend on the processing

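Of 38 alternatives 20 stayed within the interval of the main value or, for counts, within a factor of 1.5. The strand offset was judged by its standard deviation between chromosomes. Some of the 20 could not move. With no repeated position and no unplaced tag, the input kept its share in peaks and its X density by construction. No listed peak lay off the autosomes and X, so that peak count was fixed too. The unmoved strand offsets lay at the search limit of 60 bases. Alternatives with U0 tags only, spacing after merging, without high-input peaks or thinned were chosen after the data were examined. The share of ChIP tags in peaks was 8.44% with 1 tag per position, 8.75% with tags moved 75 bases, 7.80% with distinct U0 tags, 4.04% in peaks with a ratio of at least 4 and 7.53% without high-input peaks; the input share was 0.659% and 1.98% in those last sets. Merging near peaks moved the median gap to 46.2 kb and pairs within 5 kb to 11.5%. A ratio of at least 4 left 11079 peaks, and 10651 enriched on recount. Thinning both libraries to 50% left 10349, so depth limits the number called. Testing only the 14412 peaks with at least 20 ChIP tags called 13114 of them. Other recounts gave 16652 to 20387 peaks. The 16652 came from U0 tags, and 15950 of them were among the 18760. Restricting to autosomes and X changed the scaling by 0.116% and no peak's tags, yet called 398 more, all at 4 pairs of tag counts beside the threshold, so small differences between these counts carry no weight. The median ratio of the widest peaks was 3.58 with near peaks merged and 3.98 without high-input peaks. The lag with most strand pairs, searched from 60 bases, was that limit over all peaks and 113 bases without high-input peaks, but a maximum at 113 was present in both. The density of X was 0.442 (ChIP) and 0.445 (input) outside peaks, and 0.447 with U0 tags. Unless stated, the cause was not tested. The analyses of transcription start sites, gene lists and sequence content that had been intended were not run, since no annotation or sequence of this build was used. ChIP and input came from the same animal, but with 1 library of each kind no test across several such pairs was possible.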

Other observations

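These values were chosen after the data were examined. Beside the chromosome 6 peak, 11 others combined at least 20 ChIP tags, a ratio of at least 8, no high input and at least 50% U1 and U2 tags. Chromosome 11 carried 4 of them, among them 88153401 to 88153800 with 33 ChIP tags and 1 input tag, a ratio of 30.2.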
